A study of Homo sapiens with 15 samples.

How the data were processed

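RNA was extracted 48 hours after the second siRNA transfection and lentiviral infection, and 3′ end libraries were made with the Lexogen QuantSeq kit, per the labels' protocols. The first siRNA was given on day 4 after the retrovirus, per the labels. The labels' genotype field speaks of knockout and knock-in, whereas their protocols describe siRNA and lentiviral METTL14; the protocols are followed here. Whether the lentiviral METTL14 escapes the siRNA, and whether siControl RAS cells carried a lentiviral vector, is not given in the sources used here. The deposited values are counts per Ensembl gene, not normalised, in 1 table of 57736 genes and 15 libraries. Bowtie2, RSEM 1.2.12 and the build hg19 are named without a role or order, per the submitters' processing notes. RSEM estimates need not be whole; every count the authors deposited is a whole number, so they may have been rounded before deposit, which is not stated. The annotation, the filters and whether counting used strand are not given in the sources used here. A 3′ method gives about 1 tag per transcript, so counts do not grow with gene length, and isoforms that share a 3′ end are not told apart.

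Gene names were matched by Ensembl ID to GENCODE 29 and to a table of gene symbols, for names alone, since that annotation is of another build; no coordinates are given. A symbol was found for 52301 IDs (90.6%), which hold 99.2% of the counts. Of these IDs 12800 were named from GENCODE, which was used where the symbol table gave no name. In 34587 genes all libraries were at 0. Total counts ran from 4917661 to 7763084 with a median of 5853195. No library was a copy of another of its group: for pairs within a group, the chi-square per degree of freedom was 3.55 to 8.95 and Pearson's correlation 0.956 to 0.968. Whether the replicate numbers pair libraries across groups was tested by correlating each library's deviation from its group mean. Over 30 pairs with the same number the correlation was -0.0541 to 0.0681, and 5 of 15 libraries went best with their own number, so the numbers were treated as unpaired.

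The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. All 15 libraries were fitted in 1 model with a coefficient for each of 5 groups in edgeR 4.0.16 (R 4.3.3), with TMM normalisation, edgeR's default expression filter and the robust quasi-likelihood F test, two-sided, on 10 residual degrees of freedom. After the filter 13516 genes were tested, which hold 99.8% of the counts, and 13150 of them have a symbol. The biological coefficient of variation was 16.7%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. Means and SD are of TMM-normalised CPM. An exact permutation test of 3 libraries against 3 cannot go below p = 0.1, so no such test was used for single genes. Comparisons were siControl RAS against control, knockdown with vector against siControl RAS, each add-back against vector, the add-backs against each other, and, for counts and lists, each add-back against siControl RAS.

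Named genes were METTL14, METTL3 and HRAS; the 5 higher and 5 lower called genes with the largest fitted change in each of 5 main comparisons, among those with a group mean of at least 10 CPM and no overlap of libraries; up to 2 called members with the largest change from each list; and 14 genes named in advance whether called or not (IL1A, IL1B, IL6, CXCL8, CXCL1, CCL2, MMP1, MMP3, CDKN1A, CDKN2A, CDKN2B, LMNB1, MKI67 and CCNA2). Some of them are left out of the text. Other members of a list are given as examples of its count and were picked after their values were seen. Of 436 genes in 19 lists, 6 matched no ID (CCL3, CCL5, MMP12, UHRF1, RBM15B and PECAM1). Lists with at least 5 tested members, 17 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison, and with an estimated correlation and fry beside it. The endothelial list (4 members) and the leukocyte list (0 members) are described only. For genes with 0 counts in a group the fold is a bound with a floor of 3 counts over the group, and for 1 to 3 counts the ratio of normalised counts is given with its exact 95% interval. Among members of the tested lists, only RSAD2, BST2 and MYH11 had 0 counts in a group, all for siControl RAS against control. Setting them at their bound left the list medians as fitted. Such a step cannot change a median while each member stays on the same side of it.

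To find how much of a change an add-back returned, the covariance of its change with the knockdown's across genes was corrected for the covariance that the shared vector libraries give alone, taken from 20 simulations, and divided by the knockdown's variance corrected in the same way. In 3 simulated draws a true return of 30% was estimated at 29.2% to 31.2% and a true return of 0% at -1.05% to 2.13%. The draws and the correction both take genes as independent. This spread therefore leaves out shifts that many genes share and does not measure the error in the real libraries. The calls of genes and lists were tested on simulated counts with 200 changed genes. For siControl RAS against control 31.3%, 56.7% and 80.3% of genes changed 1.5-fold, 2-fold and 4-fold were recovered among 13141 genes, for the knockdown 31.3%, 64.2% and 80.3% among 13206, for wild type 28.4%, 62.7% and 72.7% among 13174, for R298P 23.9%, 55.2% and 77.3% among 13172, and for wild type against R298P 29.9%, 55.2% and 78.8% among 13224. Between 5 and 10 other genes were called and 0 with a wrong sign. A list shifted 1.5-fold was called in each simulated comparison, with 0 other lists called. These counts too were drawn for each gene independently, so they cannot test false list calls that come from correlated genes.

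The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no low-count filter, a filter of 5 CPM in 3 libraries, only the 6 libraries compared, the replicate number as a block, a fold minimum of 2, and each library left out in turn. Leave-outs for the return of the knockdown change and for the genes changed by RAS, list medians without each library, simulations of no and of full return for the genes called in the knockdown, and 10 gene families defined by symbol, were added after the data were seen. For each comparison all 10 splits of its 6 libraries were fitted.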

Results

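Gene expression was measured in IMR90 cells, a line of human fetal lung fibroblasts, in 15 libraries that fall into 5 groups of 3. One group, called control below, carried an empty retrovirus and a non-targeting siRNA. The other groups expressed RAS, an oncogene that drives fibroblasts into senescence, a lasting stop of division with secretion of cytokines, growth factors and proteases (the senescence-associated secretory phenotype, SASP). The RAS groups received the non-targeting siRNA (siControl RAS cells), an siRNA against METTL14 with a lentiviral vector (knockdown cells), or that siRNA with lentiviral wild-type METTL14 or METTL14 with the R298P substitution (the add-back groups). METTL14 is the partner of METTL3 in the complex that writes N6-methyladenosine (m6A) on RNA, and R298P is known to lower the activity of that complex. Total counts lay between 5677742 and 6124671 in control, 5611724 and 7763084 in siControl RAS, 4917661 and 6441349 in knockdown, 5023359 and 6736809 in wild-type and 4953042 and 6271500 in R298P libraries. One count therefore stood for 0.129 to 0.203 CPM, the unit of counts scaled to the size of the library. Levels below are mean normalised CPM ± SD with n = 3 libraries, fold changes are given as log2 unless named as a fold, and a gene is called changed at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's two-sided quasi-likelihood test over 13516 genes. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure a spread between libraries that can be technical. Intervals and floors given for genes with few counts cover counting error only.

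The first principal component held 42.4% of the variance and parted control libraries (-94.2 to -90.4) from RAS libraries (11.2 to 41.6). Within the RAS libraries, the siControl group lay farthest from control on this component, and the knockdown and add-back groups lay between. On the second, which held 9.56% of the variance, siControl RAS libraries stood at 36.45 to 40.94 and control libraries at 8.43 to 9.32. The knockdown and add-back libraries stood at -29.25 to -10.21, so on that component they lay beyond control and not between. On the third component, which held 5.52% of the variance, replicate 1 of the knockdown group stood at 54.4 and the other libraries between -25.6 and 9.88. On the fourth, which held 4.83%, replicate 3 of the siControl RAS, wild-type and R298P groups stood at -23.1, -32.6 and -25.7 and the other libraries between -5.40 and 25.3. Without replicate 1 of the knockdown group 1753 genes were called for the knockdown, 70 for wild-type METTL14 and 140 for R298P, against 2100, 84 and 148 with it.

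METTL14 (ENSG00000145388) was measured first, since it checks the labels. Its level was 21.2 ± 2.11 CPM in control and 22 ± 3.66 CPM in siControl RAS cells, a log2 difference of 0.07 (adjusted p = 0.775). The knockdown libraries had 9.35, 4.94 and 3.94 CPM, a 3.77-fold fall against siControl RAS cells (adjusted p = 5.49e-06). With add-back it reached 545 ± 32.0 CPM for wild type and 945 ± 80.4 CPM for R298P, 24.6-fold and 42.5-fold above siControl RAS cells. Tags from the endogenous gene and from the lentivirus were not separated, so the residual endogenous level in the add-back groups is not known. METTL3 (ENSG00000165819), the catalytic partner, had 15.8 ± 0.967 CPM in control and 12.3 ± 6.19 CPM in siControl RAS cells and was not called in any of the 7 comparisons. Without replicate 2 of siControl RAS cells, METTL3 was called lower than in control, by 0.85 on the log2 scale. HRAS (ENSG00000174775) fell from 57.8 ± 5.28 CPM in control to 40.2 ± 4.14 CPM in siControl RAS cells, by 0.52 on the log2 scale (adjusted p = 0.00360). The labels do not name the RAS isoform, and tags from the 3′ end of a transcript can miss a transgene, so this value does not measure the oncogene.

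**Figure D1:**
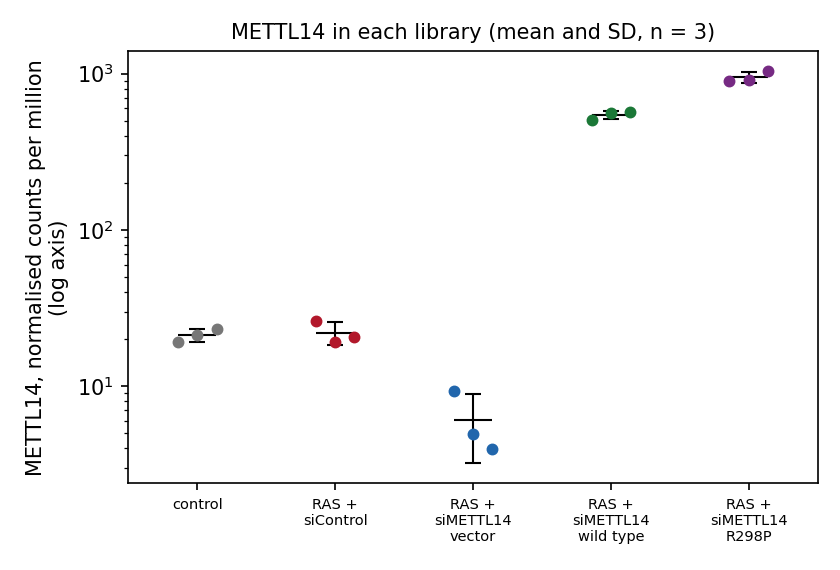
METTL14 in normalised CPM on a log axis, with a point for each library of the 5 groups and the mean ± SD in black. The knockdown libraries lie between 3.94 and 9.35 CPM, below the 2 groups with control siRNA, and the add-back means are 545 and 945 CPM.

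The comparison of siControl RAS cells with control asks what RAS-induced senescence did to the transcriptome. Cytokines of the SASP rose steeply and genes of cell division nearly vanished. CXCL1, a neutrophil chemokine, went from 1.91 ± 1.27 to 1693 ± 76.7 CPM, IL1B from 0.878 ± 0.848 to 695 ± 78.3 CPM and IL6 from 0.374 ± 0.233 to 56.6 ± 9.58 CPM. MKI67, the marker of proliferating cells, fell from 284 ± 19.6 to 10.3 ± 3.44 CPM, 27.7-fold. LMNB1, a nuclear lamina protein lost in senescence, fell from 81.8 ± 9.33 to 5.89 ± 0.847 CPM, 13.8-fold. In all 6201 genes were called, 3241 higher and 2960 lower (3073 and 3169 with upper-quartile factors, which turns the balance), of which 1656 and 1157 changed at least 2-fold. The libraries did not overlap in 5947 of the called genes and in 54.2% of all tested genes, where chance gives 10%.

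Secreted factors were higher in most fixed lists, each tested with camera. Among 23 SASP cytokines and chemokines, 19 rose and 1 fell, with a median log2 change of 6.30 (adjusted p = 1.11e-41). CXCL8 rose 311-fold to 867 ± 35.7 CPM, and the monocyte attractant CCL2 rose 8.49-fold to 101 ± 14.1 CPM. CSF3, the granulocyte growth factor, had 1 count over the control libraries and 160 ± 10.9 CPM in RAS cells, a ratio of 2949 with a 95% counting interval of 529 to 116509. IL1A had 3 control counts and 124 ± 13.1 CPM in RAS cells, a ratio of 768 with an interval of 263 to 3729. CXCL12, a chemokine of resting fibroblasts, was the exception and fell by 7.04 on the log2 scale, from 52.3 ± 4.32 to 0.332 ± 0.430 CPM. CXCL1, CXCL2 and CXCL3 are close paralogs, so their shares of the reads are less certain than their sum. Of 23 growth factors and binding proteins, 18 rose and 2 fell (median 1.83, adjusted p = 4.64e-40). AREG, an EGF receptor ligand, rose by 6.98 to 652 ± 21.02 CPM and BMP2 by 4.76 to 275 ± 32.0 CPM, while IGFBP6 fell by 1.23. Of 17 proteases and protease regulators, 13 rose and 3 fell (median 1.17, adjusted p = 8.57e-12). The collagenase MMP1 rose 7.97-fold to 1241 ± 17.99 CPM and the stromelysin MMP3 29.4-fold to 623 ± 73.3 CPM.

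Regulators of inflammation and interferon-stimulated genes were also higher. Of 21 NF-kB and C/EBP genes, 19 rose and 0 fell (median 2.22, adjusted p = 3.35e-32). They include the prostaglandin synthase PTGS2 (82.9-fold, to 957 ± 37.5 CPM), the mitochondrial superoxide dismutase SOD2 (log2 3.9), the adhesion receptor ICAM1 (4.80) and CEBPB (1.36). Another member, VCAM1, had 1 control count, a ratio of 54.6 with an interval of 9.39 to 2195. Of 29 interferon-stimulated genes, 26 rose and 0 fell (median 2.85, adjusted p = 9.19e-15), among them MX1 (4.75) and ISG15 (3.05). BST2, which tethers budding virus, had 0 control counts and was at least 179-fold higher, with the floor set at 3 counts over the group. OAS2 had 1 control count, a ratio of 447 with an interval of 79.8 to 17681. Of 21 MAPK feedback genes and ERK targets, 9 rose and 4 fell (median 0.28, adjusted p = 1.40e-04). FOS rose by 6.26 and EGR1 by 2.81, both early targets of ERK, as did the ERK phosphatases DUSP4 (2.14) and DUSP6 (1.78), while FOSL1 fell by 1.61. EGR2 had 2 control counts, a ratio of 39.9 with an interval of 10.7 to 335.

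Genes of division fell as a block. All 28 mitosis genes fell, with a median of -4.35 (adjusted p = 4.44e-47), and all 26 DNA replication genes fell, with a median of -2.82 (adjusted p = 1.48e-18). CDC20, which activates the anaphase-promoting complex, fell by 5.29, CCNA2 by 4.63, and the replication factors MCM10 and GINS2 by 5.02 and 4.88. CENPA, the centromeric histone, had 1 count over the RAS libraries, a ratio of control to RAS of 268 with an interval of 47.7 to 10631. TROAP, KIF18B and ID4 had 0 counts in RAS cells and were at least 107-fold, 69.9-fold and 63.7-fold lower. Of 21 CDK inhibitors and p53 targets, 15 rose and 1 fell (median 0.69, adjusted p = 9.92e-04). CDKN1A (p21) rose 2.58-fold to 1771 ± 87.2 CPM, CDKN2B (p15) 14.7-fold to 49.4 ± 6.56 CPM and CDKN2A, whose tags do not part p16 from ARF, 1.85-fold to 167 ± 9.60 CPM. RRM2B, a p53-regulated subunit of ribonucleotide reductase, rose by 1.51 and BAX fell by 0.68. Of 20 chromatin and nuclear envelope genes, 14 fell and 0 rose (median -1.27, adjusted p = 3.06e-11), including HMGB2 (-3.65) and EZH2 (-2.59).

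Matrix, lysosome and metabolic lists moved as well. Of 31 extracellular matrix genes, 29 rose and 1 fell (median 1.52, adjusted p = 4.55e-40). POSTN rose by 5.51, LUM by 4.21 and COL3A1 by 3.23, while elastin (ELN) fell by 4.97. Of 28 lysosomal genes, 17 rose and 2 fell (median 0.61, adjusted p = 7.60e-06). The cathepsins CTSS and CTSK rose by 7.20 and 3.92, and GLB1, the beta-galactosidase behind the usual senescence stain, by 1.04. Of 24 unfolded protein and ATF4 response genes, 13 rose and 4 fell (median 0.44, adjusted p = 0.0379), with VLDLR at 3.25, ATF3 at 2.71 and the cystine transporter SLC7A11 at -0.91. Of 21 cholesterol synthesis genes, 1 rose and 13 fell (median -0.59, adjusted p = 9.85e-04), including MVK (-2.08). Among 22 contractile and YAP/SRF genes, 9 rose and 9 fell. That list was not called (adjusted p = 0.347), and its median of -0.0015 and mean of 0.43 differ in sign; the median ran from -0.04 to 0.10 when any 1 of the 6 libraries was left out. TGFB2 rose by 2.17, ANKRD1 fell by 1.66, and MYH11, with 0 control counts, was at least 11.1-fold higher. Of 20 m6A writers, erasers and readers, 3 rose and 5 fell (median -0.14, and -0.09 without siControl RAS replicate 1; adjusted p = 0.454). The writer subunit WTAP rose by 0.84, the demethylase FTO by 1.08 and the reader HNRNPA2B1 fell by 0.97. Without replicate 3 of control, FTO was no longer called. Adjusted over the list alone, the counts were the same for every list except MAPK (11 rose, 4 fell), cholesterol synthesis (1 rose, 15 fell) and endothelial markers (3 rose, 0 fell). All list calls of this comparison held with an estimated correlation between genes in camera, at larger adjusted p (1.70e-05 for SASP cytokines).

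Markers of other cell types were mixed, with many at 0 counts and some well expressed, such as KRT19 at up to 61.2 CPM in a library and TEK at up to 38.9 CPM. Of 14 epithelial markers 5 were measured well enough to test; 2 rose (ELF3 and CLDN7) and 2 fell (KRT19 by 2.31 and CLDN4 by 2.03), the same 2 and 2 adjusted over the list alone. That list was not called (adjusted p = 0.556; median -0.21, mean 0.46, direction down). Its median was -0.03, -0.09 and -0.48 without control replicates 1, 2 and 3, and -0.05 and -0.35 without siControl RAS replicates 1 and 3. ELF3, an epithelial transcription factor, had 2 control counts, a ratio of 47.5 with an interval of 12.8 to 398. CDH1, KRT5 and KRT14 had 0 counts in all 15 libraries. Among 4 endothelial markers TEK rose by 0.66 and ROBO4 by 1.94, with 3 higher adjusted over the list alone, and CDH5 and ERG had 0 counts. No leukocyte marker was tested; PTPRC had at most 2 counts in a library and CD14 at most 15.

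**Figure D2:**
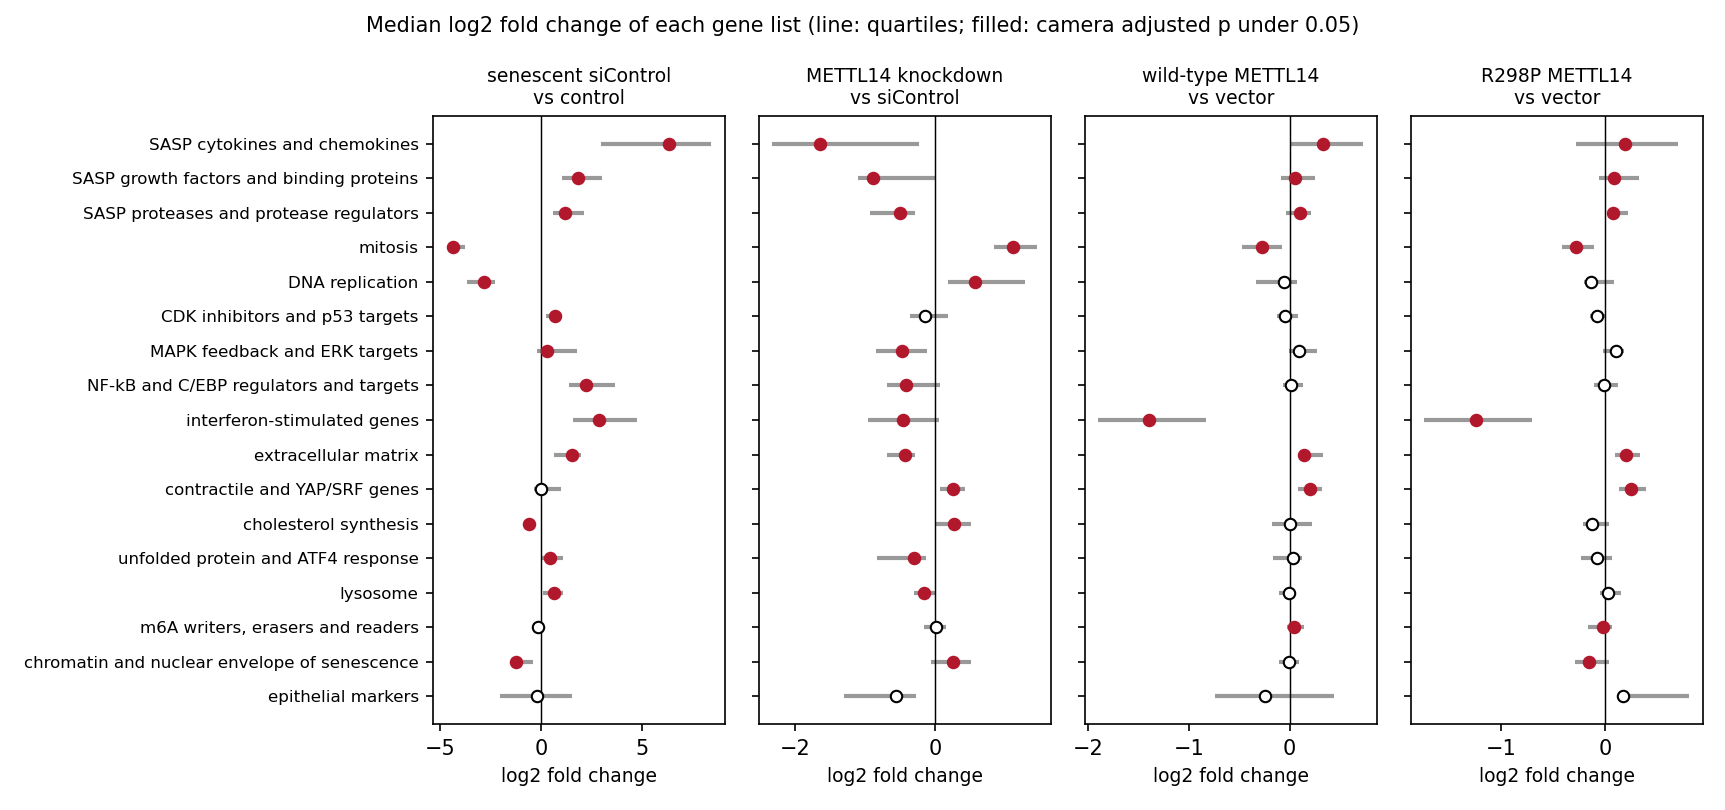
Median log2 fold change of each fixed gene list in 4 comparisons, with grey lines for the quartiles and filled red points for lists called by camera at an adjusted p under 0.05. The horizontal axes differ between panels; SASP cytokines had medians of 6.30, -1.65, 0.33 and 0.20 for RAS, knockdown, wild type and R298P.

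The knockdown comparison asks which part of the senescent programme depended on METTL14. In knockdown cells SASP genes were lower and division genes higher than in siControl RAS cells. IL11, a cytokine of the IL6 family, fell from 811 ± 47.8 to 63.8 ± 1.35 CPM, 12.7-fold (adjusted p = 1.97e-25), and AREG from 652 ± 21.02 to 40.8 ± 5.64 CPM, 15.9-fold. IL1B fell 4.41-fold to 158 ± 25.1 CPM and IL6 5.70-fold to 9.78 ± 3.94 CPM. MKI67 rose 4.01-fold to 41.0 ± 3.47 CPM, still below the 284 ± 19.6 CPM of control. In all 2100 genes were called, 1010 higher and 1090 lower (1168 and 970 with upper-quartile factors, which turns the balance), of which 188 and 325 changed at least 2-fold. The libraries did not overlap in 2026 of them and in 29.99% of all tested genes, where chance gives 10%.

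Of the SASP cytokines and chemokines 14 fell and 0 rose (15 fell adjusted over the list alone; median -1.65, adjusted p = 2.79e-41). CXCL8 fell by 1.87 to 236 ± 49.6 CPM, CXCL1 by 1.75 to 502 ± 83.4 CPM, IL1A by 1.81 to 35.3 ± 5.12 CPM and CCL20, an attractant of dendritic and T cells, by 5.01. CCL2 had 123 ± 42.3 against 101 ± 14.1 CPM and was not called (adjusted p = 0.631). Of the growth factors and binding proteins 14 fell and 2 rose (16 and 2 adjusted over the list alone; median -0.90, adjusted p = 7.72e-32). EREG fell by 1.97, INHBA by 1.19 and VEGFA by 1.04, while FGF1 rose by 0.86. Of the proteases and their regulators 12 fell and 2 rose (13 and 3 adjusted over the list alone; median -0.50, adjusted p = 1.36e-14). MMP3 fell 4.87-fold to 128 ± 17.1 CPM, MMP1 1.91-fold to 649 ± 13.5 CPM and MMP10 by 4.13. The elastase inhibitor PI3 and the G protein regulator RGS5, outside the lists, fell by 5.23 and 3.74.

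Several other lists were lower as well. Of the NF-kB and C/EBP list 10 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.42, adjusted p = 6.02e-08). PTGS2 fell 8.20-fold to 117 ± 14 CPM, and NFKBIZ and CEBPB by 0.99 and 0.90, whereas VCAM1 rose 6.55-fold to 19.2 ± 4.17 CPM. Of the MAPK list 8 fell and 1 rose (9 and 2 adjusted over the list alone; median -0.47, adjusted p = 1.06e-07), with FOS at -1.66, EGR1 at -1.63 and DUSP4 at -0.92. Of the interferon-stimulated genes 4 fell and 1 rose, the same adjusted over the list alone (median -0.46, adjusted p = 9.59e-05). These were BST2 (-3.29), IFI27 (-2.81), IFI44L (-1.45) and IFI6 (-1.45), and the RNA sensor RIGI (0.40). Of the matrix genes 24 fell and 1 rose (25 and 2 adjusted over the list alone; median -0.44, adjusted p = 4.71e-22), with LUM at -1.33, COL8A1 at -1.29, FN1 at -1.15 and FBN2 at 0.74. Of the unfolded protein and ATF4 list 10 fell and 1 rose (12 and 1 adjusted over the list alone; median -0.30, adjusted p = 1.16e-04), with DDIT4 at -1.54, PSAT1, an enzyme of serine synthesis, at -1.50 and TRIB3 at -1.39.

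The mitosis list rose, with 18 higher and 0 lower (23 and 0 adjusted over the list alone; median 1.10, adjusted p = 1.31e-16). BUB1B, a kinase of the spindle checkpoint, rose by 2.01, CDC20 by 1.60 and CCNA2 by 1.38. CENPA had 21 counts against 1, a ratio of 21.96 with an interval of 3.53 to 908. The DNA replication list rose, with 8 higher and 0 lower (12 and 0 adjusted over the list alone; median 0.57, adjusted p = 6.21e-05), and the transcription factor MYBL2 rose by 2.36. The chromatin list rose, with 9 higher and 0 lower either way (median 0.25, adjusted p = 0.00220). LMNB1 was 9.42 ± 0.932 CPM, 0.66 above siControl RAS cells (adjusted p = 0.0420), against 81.8 ± 9.33 CPM in control. CENPA and CCNA2 were not called by limma-voom and LMNB1 neither by it nor by DESeq2; CCNA2 was also not called without siControl RAS replicate 3 or knockdown replicate 2, and LMNB1 not without siControl RAS replicate 2 or 3 or knockdown replicate 1 or 2. The CDK inhibitors and p53 targets were not called as a list (2 rose and 3 fell either way; adjusted p = 0.454). CDKN1A fell 1.28-fold to 1379 ± 76.5 CPM and CDKN2B 1.5-fold to 32.9 ± 7.65 CPM, while CDKN2A had 164 ± 27.2 against 167 ± 9.60 CPM (adjusted p = 0.945). CDKN2B was not called without siControl RAS replicate 2 or without knockdown replicate 1 or 3.

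Contractile and YAP/SRF genes rose, with 9 higher and 2 lower (10 and 3 adjusted over the list alone; median 0.26, adjusted p = 9.69e-04), among them ANKRD1 at 1.07 and CNN2 at 0.68. Cholesterol synthesis genes rose, with 6 higher and 0 lower either way (median 0.26, adjusted p = 0.00125). Without knockdown replicate 2 the cholesterol median was 0.43 and the lysosome median -0.10. In the lysosome list 6 genes fell and 1 rose (8 and 1 adjusted over the list alone; median -0.17, adjusted p = 0.00715). The lysosome list was not called with an estimated correlation (adjusted p = 0.0615 with an estimated correlation). The other list calls of this comparison held in camera, at larger adjusted p (1.72e-05 for SASP cytokines). CTSS fell by 1.45 and CTSK by 0.65. METTL14 was the only called member of the m6A list (adjusted p = 0.732; median 0.01, and -0.04 to 0.04 without any 1 of the 6 libraries; mean -0.08). Among epithelial markers ELF3 and CLDN7 fell by 4.41 and 1.31 and KRT19 rose by 1.23 (list adjusted p = 0.390). CLDN7 was not called when any 1 of the 6 libraries was left out. The oxytocin receptor OXTR, the guidance cue SLIT2 and PKD1L1-AS1 rose by 2.65, 2.23 and 2.48; the last is an antisense gene whose tags may belong to its partner, since the counting is not stated to use strand. The siControl RAS cells are not described as carrying a lentivirus, so the comparison can include an effect of the vector or of the siRNA itself.

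**Figure D3:**
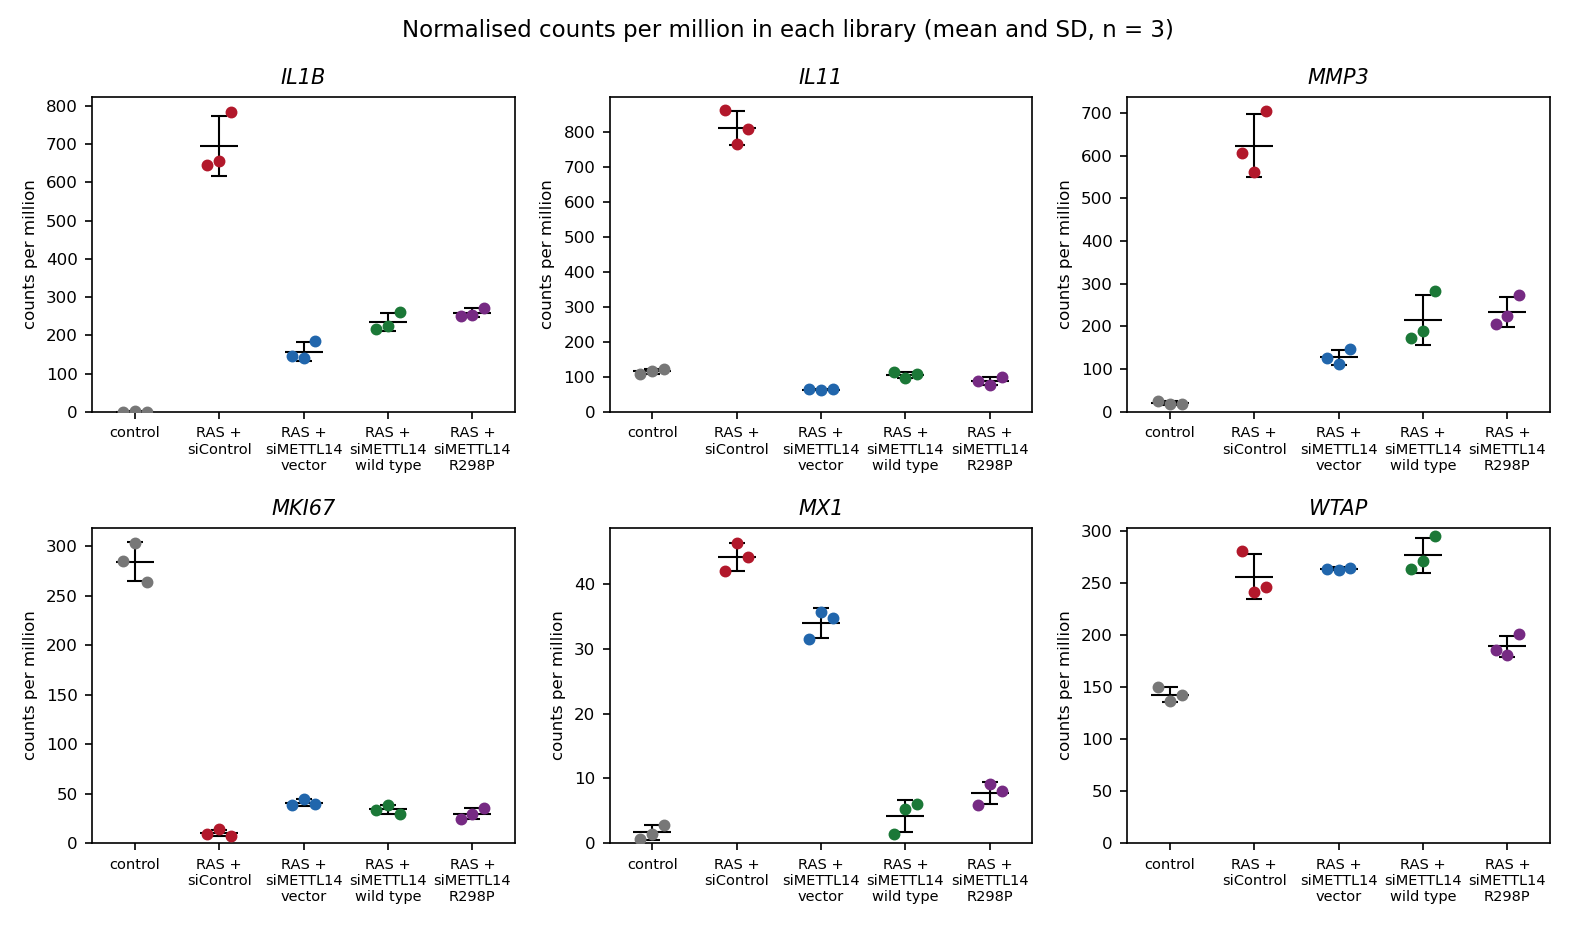
Normalised CPM of IL1B, IL11, MMP3, MKI67, MX1 and WTAP, with a point for each library of the 5 groups. IL11 averages 811 CPM in siControl RAS cells and 63.8 CPM after knockdown, MX1 34.0 CPM with vector and 4.22 CPM with wild-type METTL14, and WTAP 276 CPM with wild type and 189 CPM with R298P.

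The genes that RAS changed were compared with those that the knockdown changed. Of the genes called in both comparisons, 1627 moved in opposite directions and 144 in the same direction, where independent calls would give 483 and 481. The 3241 genes higher with RAS had a median of -0.28 in the knockdown, with 898 called lower and 101 higher. The 2960 genes lower with RAS had a median of 0.27, with 729 called higher and 43 lower. The siControl RAS libraries are in both comparisons, which alone gives an opposite movement. In 20 simulations with those shared libraries and no knockdown effect the medians averaged -0.0261 and 0.0319. The covariance across genes was -0.410 against -0.0655 simulated.

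The wild-type add-back asks whether METTL14 restores what the knockdown changed. Interferon-stimulated genes were lower than with vector, while a few secreted, matrix and contractile genes were higher. By list medians, interferon-stimulated and contractile genes moved on in the direction of the knockdown (-0.46 and 0.26 there) and not back. Single members could differ from their list. ACTA2 had fallen by 0.30 in the knockdown, and the matrix gene FBN2 had risen by 0.74. MX1, an antiviral GTPase, fell from 34.0 ± 2.25 to 4.22 ± 2.46 CPM and IFI27 from 29.1 ± 5.15 to 7.18 ± 1.25 CPM. CXCL6 rose 2.47-fold to 50.6 ± 2.66 CPM, IL11 from 63.8 ± 1.35 to 106 ± 8.47 CPM, and smooth muscle actin (ACTA2) 1.43-fold to 638 ± 39.9 CPM. In all 84 genes were called, 44 higher and 40 lower (40 and 41 with upper-quartile factors), of which 6 and 13 changed at least 2-fold. The libraries of both groups lay apart in all of the 84 and in 13.04% of all tested genes, where chance gives 10%.

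Of the interferon-stimulated genes 12 fell and 0 rose (19 and 0 adjusted over the list alone; median -1.40, adjusted p = 1.61e-71), among them IFI44L (-3.13), IFIT1 (-2.46), OAS2 (-2.27) and XAF1 (-2.01). Of the SASP cytokines 3 rose and 0 fell (11 and 2 adjusted over the list alone; median 0.33, and 0.52 without vector replicate 3; adjusted p = 4.27e-11). These were CXCL6 (1.31), CSF3 (0.75) and IL11 (0.73). CXCL1 had 857 ± 32.7 against 502 ± 83.4 CPM (adjusted p = 0.0721), CXCL8 394 ± 25.3 against 236 ± 49.6 CPM (adjusted p = 0.114), IL1B 234 ± 23.2 against 158 ± 25.1 CPM (adjusted p = 0.141) and MMP3 215 ± 59.1 against 128 ± 17.1 CPM (adjusted p = 0.235). None of these 4 passed the test in edgeR, and all were called by DESeq2 and by limma-voom. IL6 had 9.73 ± 1.09 against 9.78 ± 3.94 CPM. Of the growth factors 3 rose and 0 fell (4 and 1 adjusted over the list alone; median 0.05, and 0.08, 0.08 and 0.03 without vector replicate 1 and wild-type replicates 1 and 3; adjusted p = 0.00621), INHBA by 0.39 and IGFBP5 by 0.31. The protease list was called (median 0.10, and 0.17 without wild-type replicate 3; adjusted p = 0.00474) with no called member (5 rose and 1 fell adjusted over the list alone). Of the matrix genes 8 rose and 0 fell (11 and 1 adjusted over the list alone; median 0.15, adjusted p = 4.32e-13), including FBN2 (0.53), THBS1 (0.40) and FN1 (0.29). Of the contractile genes 6 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.20, adjusted p = 3.84e-09), including CCN2 (0.44), a YAP target, and TAGLN (0.33). The mitosis list fell (median -0.27, adjusted p = 3.70e-05), with CCNB1 its called member (-0.76; 0 rose and 3 fell adjusted over the list alone). MKI67 had 34.1 ± 4.62 against 41.0 ± 3.47 CPM (adjusted p = 0.748) and CDKN1A 1460 ± 63.7 against 1379 ± 76.5 CPM (adjusted p = 0.831). The m6A list was called upward (adjusted p = 5.37e-10) with a median of 0.04 and a mean of 0.35, through METTL14 itself. The decoy receptor TNFRSF10D rose 2.03-fold to 285 ± 19.7 CPM, CST1 by 1.24 and CST4 by 1.27; the last 2 are near-identical cystatins whose reads can be exchanged.

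All of these list calls held with an estimated correlation in camera, at larger adjusted p (2.42e-07 for interferon-stimulated genes and 0.00366 for SASP cytokines). In edgeR 55 genes were called without wild-type replicate 2. The call of CST4 was lost without any 1 of the 6 libraries, that of CSF3 without vector replicate 2 or 3 or wild-type replicate 2 or 3, that of FBN2 without vector replicate 3 or wild-type replicate 2 or 3, that of CCN2 without vector replicate 1 or 3 or wild-type replicate 1 or 2, and that of CCNB1 without vector replicate 3 or wild-type replicate 2 or 3. CXCL8 and IL1B were called without vector replicate 3, and each of these genes kept its direction.

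The R298P add-back asks the same with a form of METTL14 known to be impaired in m6A writing. Apart from the m6A list, whose call in both rests on the added METTL14 itself, every list called with wild type was also called with R298P in the same direction, and the chromatin list besides. The interferon and contractile lists thus again moved on in the direction of the knockdown. The same vector libraries are in both comparisons, which alone gave a correlation across genes of 0.496 in 20 simulations with no add-back effect, against 0.589 found. MX1 fell to 7.73 ± 1.69 CPM and IFI27 to 8.10 ± 1.67 CPM, both from the vector levels given above. RGS5 rose 3.11-fold to 49.4 ± 2.81 CPM, CXCL6 2.31-fold to 47.2 ± 3.8 CPM and ACTA2 1.52-fold to 679 ± 33.1 CPM. In all 148 genes were called, 73 higher and 75 lower, of which 9 and 16 changed at least 2-fold. The libraries did not overlap in 146 of them and in 15.01% of all tested genes, where chance gives 10%.

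Of the interferon-stimulated genes 12 fell and 0 rose (20 and 0 adjusted over the list alone; median -1.24, adjusted p = 1.42e-53), among them MX2 (-3.69), OAS2 (-2.11) and IFIT1 (-1.91), and HERC6, an interferon-induced gene outside the list, fell by 2.05. Of the SASP cytokines 4 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.20, and 0.34 without vector replicate 3; adjusted p = 1.59e-08). These were CXCL6 (1.21), CSF3 (0.81), IL1B (0.71, adjusted p = 0.0236) and IL11 (0.47). CXCL8 had 403 ± 27.4 CPM (adjusted p = 0.0551), MMP3 234 ± 35.4 CPM (adjusted p = 0.0793) and CXCL1 792 ± 127 CPM (adjusted p = 0.103); all 3 were called by DESeq2 and by limma-voom. Of the growth factors 4 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.09, and 0.16 without vector replicate 1; adjusted p = 4.92e-05), including AREG (0.98) and INHBA (0.41). Of the proteases 3 rose and 1 fell (7 and 2 adjusted over the list alone; median 0.08, and 0.17 to 0.19 without vector replicate 2 or 3 or R298P replicate 1 or 3; adjusted p = 6.13e-04), with MMP10 at 2.18 and ADAMTS1 at -0.42. Of the matrix genes 10 rose and 0 fell (12 and 1 adjusted over the list alone; median 0.20, adjusted p = 5.95e-13), including FBN2 (0.64) and COL4A2 (0.50). Of the contractile genes 3 rose and 0 fell (11 and 0 adjusted over the list alone; median 0.25, adjusted p = 1.25e-11), including tropomyosin TPM1 (0.46). The mitosis list fell (median -0.28, and -0.18 without R298P replicate 1; adjusted p = 1.78e-05) with no called member (0 rose and 5 fell adjusted over the list alone), and MKI67 had 29.6 ± 5.49 CPM (adjusted p = 0.154). The chromatin list fell (median -0.15, adjusted p = 0.00520; 1 fell, HMGA1 by 0.26, and 2 adjusted over the list alone). In the m6A list METTL14 rose while WTAP and IGF2BP3 fell by 0.48 and 0.38; the list was called upward (adjusted p = 1.04e-05) with a mean of 0.33, but its median was -0.02, and -0.03 and -0.04 without R298P replicates 1 and 3. From the unfolded protein list CHAC1 rose by 0.51, and outside the lists CST1 and PARP6 rose by 1.17 and 1.07.

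All of these list calls held with an estimated correlation in camera, at larger adjusted p (2.42e-06 for interferon-stimulated genes and 0.00753 for SASP cytokines). Without R298P replicate 2 or 3, 93 and 90 genes were called. The call of IL1B was lost in 5 of the 6 leave-outs, all but that of vector replicate 3. That of PARP6 was lost without vector replicate 1 or R298P replicate 2 or 3, that of IFIT1 without vector replicate 2 or R298P replicate 1 or 2, that of MX2 without R298P replicate 1 or 3, that of MMP10 without vector replicate 2 or 3 or R298P replicate 1 or 3, that of ADAMTS1 without vector replicate 2 or R298P replicate 3, and that of HMGA1 without vector replicate 1 or 3 or R298P replicate 1 or 3. CXCL8 was called without vector replicate 3 and CXCL1 without R298P replicate 3, and each of these genes kept its direction.

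**Figure D4:**
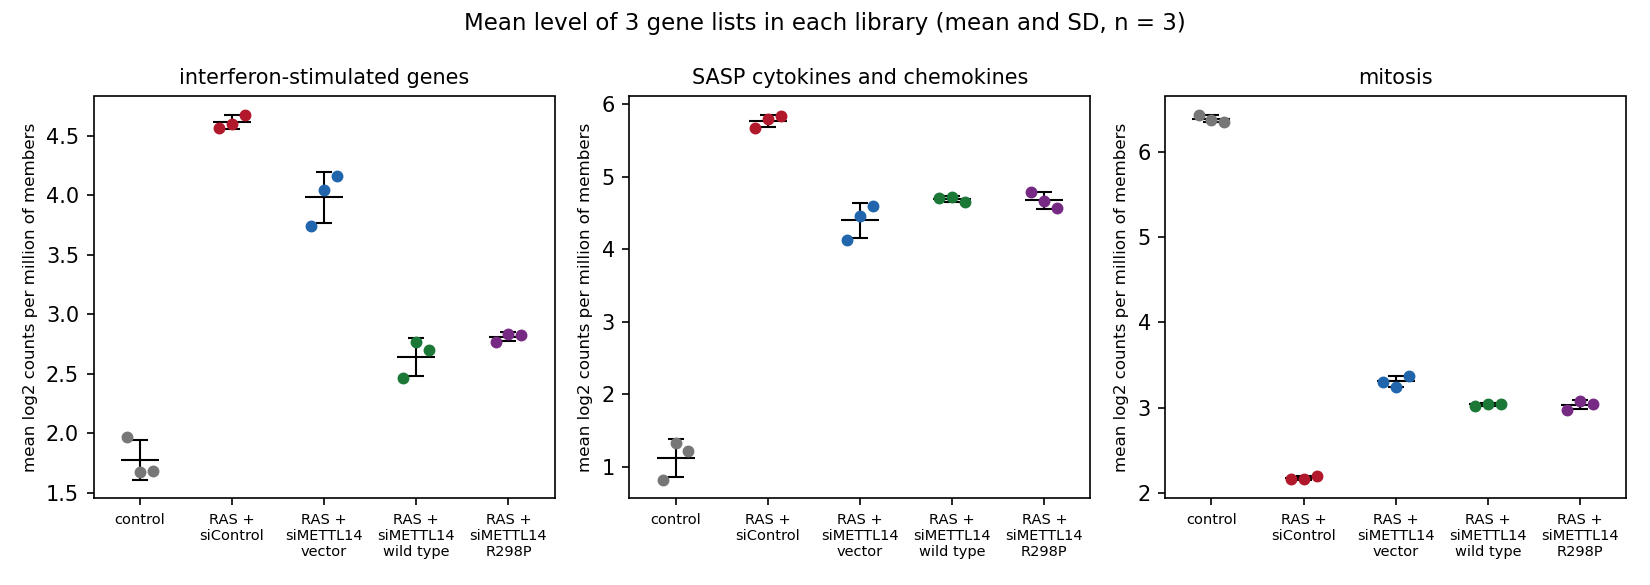
Mean log2 CPM of the interferon-stimulated genes, SASP cytokines and mitosis genes, with a point for each library; the vertical axes do not start at 0. Interferon-stimulated genes average 1.77 in control, 4.62 in siControl RAS, 3.98 in knockdown, 2.64 in wild-type and 2.81 in R298P libraries.

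The direct comparison of both add-backs asks whether the substitution changed the outcome. Only 3 genes were called in edgeR, with 665 at an unadjusted p under 0.05. WTAP (ENSG00000146457), the regulatory subunit of the m6A writer, had 276 ± 16.5 CPM with wild type and 189 ± 10.51 CPM with R298P, 1.46-fold higher with wild type (adjusted p = 5.49e-04). RCAN1 (ENSG00000159200), an inhibitor of calcineurin, had 734 ± 19.1 against 574 ± 20.01 CPM (log2 0.35, adjusted p = 0.0225). METTL14 was 1.73-fold lower with wild type (adjusted p = 0.0322). None of the 17 lists tested was called, and the lowest adjusted p was 0.155, for chromatin genes. The SASP cytokines had a median of 0.06 (adjusted p = 0.590) and the interferon-stimulated genes of -0.11 (adjusted p = 0.272), with 0 members called either way, also adjusted over the list alone. The SASP median was 0.02 without wild-type replicate 3 and 0.12, 0.13 and 0.04 without R298P replicates 1, 2 and 3, and the interferon median -0.17 without wild-type replicate 1. IL1B had 234 ± 23.2 against 258 ± 11.8 CPM, CXCL8 394 ± 25.3 against 403 ± 27.4 CPM and CDKN1A 1460 ± 63.7 against 1395 ± 51.0 CPM. The libraries did not overlap in 11.7% of genes, where chance gives 10%. WTAP kept its call without each of the 6 libraries, whereas RCAN1 (log2 0.33 to 0.38) and METTL14 (-0.83 to -0.72) lost theirs without any 1 of them.

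Both add-backs were set against the knockdown to ask how much came back. Of the genes called in the knockdown, 50 were called in the opposite direction with wild type and 8 in the same direction, and 94 and 10 with R298P. Independent calls would give 6.54 and 11.49 opposite ones. The vector libraries are in both comparisons; 20 simulations with that sharing and no add-back effect gave 0.15 opposite genes on average and at most 1. METTL14 is among the 50 and the 94, with IL11, CSF3, CXCL6, INHBA, FN1 and THBS1 higher again and SP100 and RIGI lower in both. SP100 and RIGI, both interferon-induced, fell by more than they had risen. They were at 0.43 and 0.40 in the knockdown, -0.56 and -0.60 with wild type and -0.62 and -0.63 with R298P. The 50 and the 94 thus include genes of the interferon shift. The 1010 genes higher in the knockdown had a median of 0.56 there, -0.09 with wild type and -0.12 with R298P, and the 1090 lower genes -0.69, 0.14 and 0.14. Since the vector libraries also served to pick these genes, medians of the opposite sign arise without any return. Simulations with none gave, on average, -0.0569 and -0.0556 for the higher genes and 0.0529 and 0.0569 for the lower ones. After subtraction of the simulated covariance, the slope across genes returned 17.8% of the knockdown change with wild type and 21.4% with R298P. Genes are not independent replicates, whereas the simulations draw each gene independently. The vector group has too few libraries to be split, so part or all of this return can come from the shared libraries. Without wild-type replicate 2 the count for wild type was 30, and without R298P replicate 2 or 3 that for R298P was 57 or 59. The correlation of the knockdown change with the difference between wild type and R298P, which share no library, was 0.0368 across genes. The covariance of this pair was 0.0085, small but above the highest of 20 simulations (0.00337 with equal groups and 0.00611 with the knockdown alone). Over all tested genes, 29 were called higher and 32 lower with both forms and 0 in opposite directions. The simulations, which share the vector libraries in the same way, gave 0.05 genes in the same direction on average and a covariance of at most 0.0734, against 0.106 found.

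Against siControl RAS cells both add-back groups were tested as well. Wild type differed in 1755 genes (854 higher, 901 lower) and R298P in 1813 (848 higher, 965 lower). With upper-quartile factors the balance turned in both, to 985 higher and 818 lower and to 989 higher and 851 lower. Of the genes higher in the knockdown, 646 (64.0%) were still called higher with wild type and 610 (60.4%) with R298P, and of those lower, 703 (64.5%) and 710 (65.1%) were still called lower. The siControl RAS libraries are in all of these comparisons. With that sharing, 20 simulations with no return of the knockdown change left 71.8% and 72.2% of the higher genes and 74.1% and 73.8% of the lower ones called, and 20 with full return at most 0.0781% of any of these sets. The simulated changes are the fitted ones and, with no return, gave 2700 knockdown calls on average against 2100 found, so these shares are no exact reference. The SASP cytokines had 15 lower and 0 higher members in each (15 adjusted over the list alone in each, with 1 higher for R298P), with medians of -1.14 and -1.10. IL6 stayed 5.79-fold and 7.30-fold below siControl RAS cells and IL1B 2.97-fold and 2.69-fold below. Interferon-stimulated genes had 19 lower members in each (24 and 23 adjusted over the list alone), with medians of -1.96 and -1.57, and mitosis genes 14 and 13 higher members (18 and 17 adjusted over the list alone), with medians of 0.90 and 0.85. Contractile genes had 14 higher and 1 lower member in each (15 and 16 higher adjusted over the list alone), with medians of 0.45 and 0.46. Cholesterol and lysosome genes were called in both, but for R298P not with an estimated correlation (adjusted p = 0.0681 and 0.105 with an estimated correlation), and the lysosome list for R298P also not without siControl RAS replicate 3.

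Genes called with RAS were last followed into the add-backs, which share no library with that comparison. The 3241 genes higher with RAS had a median of 0.04 with wild type, with 33 called higher and 25 lower, and 0.04 with R298P, with 59 called higher and 34 lower. The 2960 genes lower with RAS had medians of -0.03 and -0.05, with 5 and 6 called higher and 10 and 25 lower. Averaged over 20 simulations with no knockdown or add-back effect, these medians were at most 0.00146 from 0. The simulations draw each gene independently, so a shift that many genes share in the vector libraries is not covered. The 43 genes called in the same direction with wild type became 27 without vector replicate 3, 26 without wild-type replicate 2 and 28 without wild-type replicate 3, and the 84 with R298P became 55 and 50 without R298P replicate 2 and 3.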

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

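The splits of the libraries were planned, and the other tests of this part were chosen after their results were seen. The wild-type and R298P add-backs differed by a test of the difference itself in 3 genes. As log2 of wild type over R298P they were METTL14 (-0.79), WTAP (0.55) and RCAN1 (0.35). RCAN1 was not called between wild type and vector (-0.02, adjusted p = 0.989 in edgeR), was lower with R298P than with vector (-0.38, adjusted p = 4.86e-04) and had risen in the knockdown (0.46, adjusted p = 1.05e-06).

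Each comparison was refitted on its 6 libraries in all 10 splits into 3 and 3, which are too few for a share under 0.05. For siControl RAS against control 1 of 10 splits, the real one, called as many genes as the real 6059, and the highest other called 0. For the knockdown it was 1 of 10 (1849, highest other 1), for wild type against vector 1 of 10 (66, highest other 3) and for R298P against vector 1 of 10 (105, highest other 3). For wild type and R298P against siControl RAS it was 1 of 10 each (1815 and 1944, highest others 2 and 0). For wild type against R298P 3 of 10 splits called at least the real 5 genes, and the highest other called 12. That split set wild-type replicates 1 and 2 with R298P replicate 1 against the rest, which points to a structure among these libraries other than the 2 groups; what it is was not tested. On the fourth principal component the same 3 libraries lay between 0.15 and 25.3 and the other 3 between -32.6 and -5.08.

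Interferon-stimulated genes were lower in both add-back groups than with vector, although the list as a whole was also lower in the knockdown than in siControl RAS cells. In the knockdown 4 of its 29 members were called lower, 1 higher and 24 were not called. Several that fell with both forms were among those not called there, such as OAS2 (-0.59), MX1 (-0.38), XAF1 (0.08) and IFIT1 (0.50). One divergent vector library is argued against, since without each vector library in turn the median stayed at -1.17 or below in both comparisons. A level that falls steadily as METTL14 transcript rises is argued against for the list as a whole, since its median in the knockdown was -0.46. This does not cover each gene. RIGI, and SP110, DTX3L and SP100 outside the list, were called higher in the knockdown and lower with both forms, as such a level would give. IFI44L, IFI27 and IFI6 were called lower in the knockdown and with both forms. A vector-borne interferon response that METTL14 does not cause may add to the level in the vector libraries and cannot be told apart from an effect of METTL14, since siControl RAS cells name no lentiviral vector, and the list's mean log2 CPM was -0.633 in vector minus siControl RAS libraries. An effect shared by both METTL14 forms stays open as the biological explanation.

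WTAP was lower with R298P than with wild-type METTL14. One divergent library is argued against, since the adjusted p was at most 0.0309 without each of the 6 libraries, over a range of 9.29e-04 to 0.0309. The scaling of the libraries is argued against, since the adjusted p was at most 5.70e-04 with RLE or upper-quartile factors. A graded response to METTL14 transcript that begins at the vector level is argued against. WTAP in vector minus wild type had a 95% interval that ended at 0.103, below the 0.55 between wild type and R298P. METTL14 was 6.53 (log2) higher with wild type than with vector, and its wild type minus R298P difference was -0.79. A response that begins only above the wild-type level is not covered. Since the R298P group also had more METTL14, such a response cannot be told apart from an effect of the substitution. A biological explanation that stays open is that the R298P protein itself may lower WTAP transcript, which these data cannot test further.

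Most of the knockdown change stayed in place with both METTL14 forms. Too little transcript in the culture as a whole is argued against, since METTL14 was at least 4.62 (log2) above siControl RAS cells in both add-back groups. Counts are means over all cells of a library, so cells left without added METTL14 cannot be told apart. Protein was not measured here. A return made only by noise of single genes in the shared vector libraries is argued against. The covariance with wild type minus the lowest simulated one was -0.0362. The simulations draw each gene independently, so a shift that many genes share in the vector libraries cannot be told apart from a return. Vector replicate 1 stood apart on the third principal component. Effects of the siRNA outside METTL14 may account for part of what did not come back. So may effects of the lentivirus, which siControl RAS cells are not described as carrying. With 17.8% of the change returned by wild type, neither can be told apart from a change fixed by the time of harvest. The design holds no other METTL14 siRNA and names no lentiviral vector in siControl RAS cells.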

How the results depend on the processing

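The leave-outs for the return of the knockdown change and for the genes changed by RAS and the medians of lists without 1 library were chosen after the data were seen, and the other alternatives of this part were planned. No called result reversed, while 48 values of uncalled named genes had another sign. Of 167 calls of named genes 141 were kept, and 52 of 66 uncalled results stayed uncalled, under each of DESeq2, limma-voom, RLE and upper-quartile factors, no and strict filter, the block, the 6 libraries alone and leave-outs (the fold minimum was not applied to single genes); the strict filter removed 3 results. Of 74 called list results 71 were called under each alternative run on lists (estimated correlation, fry, RLE factors, the block and leave-outs). Of 45 uncalled list results 31 stayed uncalled under each of them, and 11 were called with fry. These 11 include contractile genes with RAS (fry adjusted p = 2.49e-07). In the knockdown they include p53 targets (fry adjusted p = 0.0298) and epithelial markers (fry adjusted p = 0.00199). With an estimated correlation the lysosome list lost its call in the knockdown and against siControl RAS cells for R298P, where it was also lost without siControl RAS replicate 3, and cholesterol synthesis lost its call for R298P against siControl RAS cells. Normalisation moved the median of all genes by at most -0.0373, for siControl RAS against control with upper-quartile factors. With the replicate number as a block 6245, 2215, 96, 182, 3, 1852 and 1908 genes were called, in the order RAS, knockdown, wild type, R298P, wild type against R298P, and wild type and R298P against siControl RAS.

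A fold minimum of 2 left 2813, 513, 19, 25, 0, 386 and 376 genes in that order, by its construction; the 0, for wild type against R298P in edgeR, stands beside 665 genes at an unadjusted p under 0.05 without that minimum. Wild type against R298P gave 12 genes with DESeq2, 14 with no low-count filter, 5 with limma-voom, 5 with only the 6 libraries compared, and 1 to 2 with 1 library left out (1 without wild-type replicate 1 or 2 or R298P replicate 2 or 3). Leaving out 1 library gave 55 to 70 genes for wild type and 90 to 140 for R298P, and 30 to 58 and 57 to 93 genes opposite to the knockdown. The lowest of these came without wild-type replicate 2 (55 and 30) and without R298P replicate 2 or 3 (93 and 90, 57 and 59). Genes higher with RAS had a median in the knockdown of -0.261 with the strict filter, -0.297 with limma-voom and -0.304 to -0.279 in leave-outs, and genes lower with RAS 0.262 with the strict filter and 0.273 to 0.312 in leave-outs. With R298P these medians were 0.0392 to 0.0538 and -0.0567 to -0.0453 in leave-outs. Genes called in the direction of RAS numbered 26 to 49 with wild type and 50 to 92 with R298P in leave-outs, with 27, 26 and 28 for wild type without vector replicate 3 and wild-type replicates 2 and 3, and 55 and 50 for R298P without R298P replicates 2 and 3. Fewer libraries give fewer calls; beyond that the cause was not tested. Depth limits the genes with few counts, where 1 count is 0.129 to 0.203 CPM.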

Other observations

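The gene families and single genes of this part were chosen after the data were seen. Transcripts of HLA class I genes rose with RAS, and part of them fell with the METTL14 knockdown. Of 13 genes of HLA class I and antigen processing 11 rose and 0 fell with RAS (median 2.35, adjusted p = 1.56e-04 with an estimated correlation in camera). B2M, the light chain of class I, went from 987 ± 34.3 CPM in control to 7427 ± 282 CPM in siControl RAS cells, and HLA-B from 74.1 to 1694 ± 119 CPM. In the knockdown 5 fell, 1 rose and the others were not called (median -0.44, adjusted p = 0.00196 with an estimated correlation), with B2M at 3504 ± 276 CPM and HLA-B at 565 ± 72.8 CPM, while the immunoproteasome subunit PSMB10 rose by 0.88. Against siControl RAS cells 9 fell and 1 rose with wild type and with R298P (medians -0.71 and -0.75, adjusted p = 1.42e-04 and 1.24e-04 with an estimated correlation); with RLE factors 0 rose with R298P. HLA class I genes are near-identical, so the share of HLA-B is less certain than the sum over them. Among the 10 families tried in 7 comparisons, these 4 results were the only calls that held with an estimated correlation. Ribosomal protein genes had 51 lower and 2 higher of 77 with RAS, which was called with the preset correlation (adjusted p = 1.51e-06) but not with an estimated one (adjusted p = 0.104 with an estimated correlation); RLE factors gave 49 lower and upper-quartile factors 55.

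The 61 genes called in the same direction with both METTL14 forms held further interferon-induced genes outside the fixed list. PARP9 fell by 1.35 with wild type and 1.11 with R298P, and IFITM3 by 0.65 and 0.65, with DTX3L, PARP14, SAMD9, SP110, SP100, SAMHD1 and EIF2AK2 lower in both. In the knockdown SP110, DTX3L and SP100 had been called higher (0.74, 0.53 and 0.43) and IFITM3 lower (-0.49). PARP9, PARP14, SAMD9, SAMHD1 and EIF2AK2 were not called there. The share of interferon-induced genes among the 61 was not tested. SFRP1, a secreted inhibitor of WNT signalling, fell by 0.56 and 0.72 after it had risen by 1.00 in the knockdown. Other genes were higher with both. The BMP antagonist GREM1 rose by 0.63 and 0.69, the neurotrophic factor GDNF by 0.85 and 0.66, and MYOCD, a coactivator of smooth muscle genes, by 0.68 and 0.62, after falls of 1.80, 2.39 and 1.38 in the knockdown.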
